A study of Mus musculus with 33 samples.

How the data were processed

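The 33 RNA sequencing libraries of mouse embryonic fibroblasts were grouped by genotype, culture and transduced gene from their titles, which gave 11 groups of 3. The authors deposited 2 tables of whole-number counts per Ensembl gene, made with HTSeq on genome build mm9. The aligner, the annotation release, the strand setting and the tool versions are not given. Each table held 37991 genes, of which 24596 and 24354 had a count, and 32919 were matched to a gene symbol. The untransduced and the transduced libraries came in separate tables and were fitted separately. Library totals were 18608693 to 29444803 counts, and the 10 most abundant genes held 3.65 to 5.43% of them. The biological coefficient of variation was 3.63% for the untransduced and 11.8% for the transduced libraries, so the second table resolves smaller changes less well.

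Counts were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Genes were tested in R 4.3.3 with edgeR 4.0.16: filtering by group (filterByExpr), TMM normalization, robust quasi-likelihood F tests on 1 model per table with a term for each group, and Benjamini-Hochberg adjustment within each comparison. This left 14284 and 13927 genes and 12 and 10 residual degrees of freedom. Normalization factors were 0.971 to 1.05. A gene passed at an adjusted p under 0.05. Differences between the responses of CRE and VEC cells were contrasts in the same model. Of 33 gene lists, 30 had at least 5 tested members in the untransduced and 28 in the transduced libraries, and these were tested in limma 3.58.1 with camera at a preset correlation of 0.01 and adjusted within each comparison. They were tested again with the correlation estimated from the residuals, which ran from -0.078 to 0.731 with a median of 0.113, and with fry. A gene whose libraries in 1 group all had 0 counts is given as a lower bound on the fold, from a floor of 3 counts over the group. With 1 to 3 counts there, the ratio is given with a 95% counting interval. In 37 pairs of list and comparison a member was at 0 in a group, and setting such members to their bounds moved a list median by at most 0.24; for 8 pairs among the differences of responses this was not recomputed.

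Groups, comparisons, lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule always names Spry1, Spry2, Spry4, Kras, Hras and Braf. In each comparison it adds the 6 largest increases and 6 largest decreases among genes that passed, whose replicates did not overlap (not asked of differences of responses) and that reached a mean of 5 CPM in the higher group, leaving out gene models without an assigned name. Between oncogenes, and between an oncogene and CRE_EV, it takes 3 in each direction. For lists that passed or are described, it adds up to 4 members that passed with the largest changes and at least 1 CPM, and up to 2 that did not pass with the highest CPM. The rule gave 2496 pairs of gene and comparison, 1694 of them past the threshold. The text names 222 of these pairs. That selection was made after the values were seen, for known function and size, and left out pairs whose call changed when a library was left out, as well as most genes that did not pass. Which lists are described in each comparison was also chosen after their results were seen, so lists and genes without a change are under-represented.

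The alternatives were DESeq2 size factors, no filter on low counts, the test of DESeq2 1.42.0, a fit of only the groups compared, replicate number as a block, counts thinned to the smallest library total, and leaving out each library in turn. Library totals as the scaling, the block with only the groups compared, and the genes shared between VEC and CRE cells in their response to FGF or starvation were added after the data were seen. Whether replicate numbers paired libraries across groups was measured as the correlation of residual log2 CPM. In the untransduced libraries it was -0.0346 to 0.0868, below the threshold of 0.1 for every pair of groups, and in the transduced libraries 9 of 10 pairs of groups were above it for each replicate number. KRas with VEC_EV was the exception, with a lowest correlation of 0.0921. Reported results are without the block. Its value stands beside them where it moved a gene count over 1.5-fold or changed a list call of such paired groups.

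The procedure was tested on simulated data with the means, library sizes and dispersions of the count tables, in which genes varied independently. With 50 genes changed by 2-fold, 50 were recovered for genotype in growing cells, 43 for HRas against VEC_EV and 46 for the difference of responses to FGF, and 13, 7 and 10 genes were called among those left unchanged. With 1.25-fold changes, 41, 6 and 26 of 50 were recovered. Of 200 unchanged lists, 0, 1 and 0 had a p under 0.05, and the changed list had a p of 1.28e-41, 1.56e-33 and 5.79e-50. Libraries were also compared pairwise within groups for duplicates, and 0 were identical. The sequences of the oncogene constructs are not given, so whether their reads count toward the mouse genes is open, and the level of each oncogene was not measured.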

Results

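RNA was sequenced from immortalized mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, in 33 libraries that fell into 11 groups of 3. The Sprouty proteins, encoded by Spry1, Spry2 and Spry4, restrain signalling from receptor tyrosine kinases through Ras to the kinase Erk. In VEC cells these 3 genes were flanked by recombination sites and intact, and in CRE cells all 3 had been deleted. Both genotypes were collected growing in serum (U), after starvation in 0.1% serum (S), and after starvation with 10 ng/ml fibroblast growth factor for the last 4 h (F), which gave 18 libraries. In 15 further libraries, growing VEC cells carried an empty vector (VEC_EV) or an oncogene, KRas G12V, HRas G12V or BRaf V600E, and CRE cells carried the empty vector (CRE_EV). Library totals ran from 21242698 to 29444803 counts in the first experiment and from 18608693 to 27974955 in the second. Gene values are CPM, counts scaled by library total and normalization factor, as mean ± SD, n = 3, and changes are on the log2 scale. Intervals and lower bounds on folds cover counting error only. Whether the 3 libraries of a group came from separate cultures or separate cell lines is not in the labels, and the series design calls them biological triplicates. The p-values therefore measure the spread between these libraries, and genotype cannot be parted from other differences between the VEC and CRE cells.

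The first question was what the deletion left of the 3 Sprouty transcripts. Spry1 (ENSMUSG00000037211) measured 0.340 ± 0.14 against 5.97 ± 1.07 CPM in growing CRE and VEC cells, Spry4 (ENSMUSG00000024427) 0.422 ± 0.0384 against 12.9 ± 0.651 CPM and Spry2 (ENSMUSG00000022114) 32.3 ± 1.59 against 124 ± 11.5 CPM. Their log2 changes were -4.13, -4.91 and -1.93. After starvation the values were 0.876 ± 0.173 against 21.8 ± 1.18 CPM for Spry1, 0.583 ± 0.0622 against 18.9 ± 3.02 CPM for Spry4 and 73.5 ± 3.01 against 196 ± 8.85 CPM for Spry2. With FGF they were 0.985 ± 0.35 against 52.3 ± 2.11 CPM, 1.32 ± 0.477 against 49.5 ± 3.71 CPM and 68.6 ± 5.04 against 336 ± 12.6 CPM in the same order. In the transduced cells they were 0.145 ± 0.0262 against 4.74 ± 0.653 CPM, 0.57 ± 0.123 against 7.39 ± 0.264 CPM and 33.5 ± 4.88 against 102 ± 8.18 CPM. Over the 12 CRE libraries, 1.42 to 7.13% of the mean VEC level of Spry1 was left, 1.81 to 9.6% of Spry4 and 18.7 to 39.3% of Spry2. The count tables hold no positions, so which part of each gene the remaining reads came from was not measured.

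**Figure D1:**
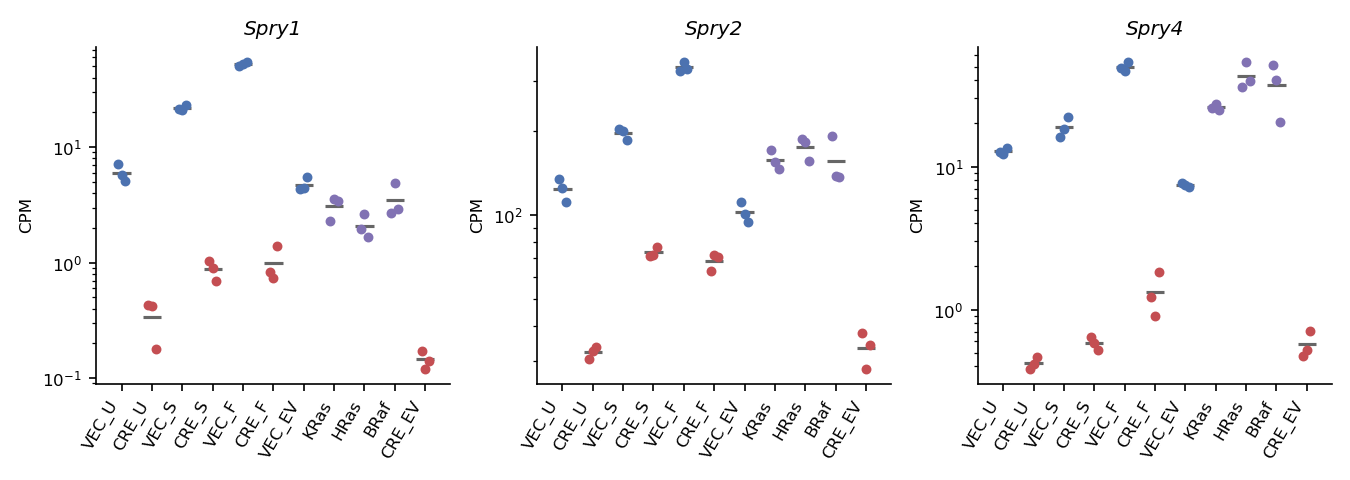
CPM of Spry1, Spry2 and Spry4 in each library on a log axis, with points for libraries and bars for the group mean, by group. All 12 CRE libraries lie below all VEC libraries of the same culture for each gene, and the remaining share is highest for Spry2, 18.7 to 39.3%.

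Growing CRE and VEC cells were compared to ask what the loss of feedback by Sprouty changes in the transcriptome without an added stimulus. The phosphatase gene Dusp4, another inhibitor that Erk induces, rose from 10.2 ± 0.721 to 41.6 ± 2.57 CPM, log2 change 2.02, and Dusp9 rose by 1.58. The FGF receptor antagonist Il17rd fell from 37.1 ± 1.02 to 12.3 ± 1.11 CPM, -1.59. The receptor gene Egfr rose from 42.2 ± 1.69 to 95.5 ± 2.82 CPM. Among growth factor genes, Pdgfb rose from 0.0454 ± 0.0469 to 5.69 ± 0.358 CPM and Tgfa from 2.21 ± 0.407 to 17.1 ± 0.966 CPM, and Fgf5 was at least 104-fold lower. The chemokine gene Ccl2, a signal for monocytes, rose from 21.4 ± 1.95 to 234 ± 10.2 CPM, and Ccl7 rose by 5.15. Serpine1, an inhibitor of plasminogen activation, rose from 142 ± 3.48 to 486 ± 27.2 CPM. Smooth muscle actin, Acta2, rose from 52.4 ± 2.76 to 452 ± 15 CPM and Tagln by 2.47. The Dickkopf family genes Dkk3 and Dkk2 fell (log2 -5.56 and -3.87), as did the Wnt transcription factor gene Lef1 (log2 -5.18). Of the largest changes, the imprinted gene Dlk1 rose from 0.554 ± 0.236 to 390 ± 21.8 CPM and the guidance gene Sema3e was at least 305-fold higher. The matrix gene Dcn fell from 129.8 ± 4.68 to 3.17 ± 0.312 CPM.

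Of 16 mesenchymal transition regulators and adhesion genes tested, 12 rose, 4 fell and 0 did not pass (12 and 4 adjusted over the list alone), median log2 change 0.65, adjusted p = 2.92e-07, or 0.0147 with an estimated correlation. The integrin gene Itgb3 rose by 4.77 and Snai1 by 1.37. Among the chemokines and cytokines, 10 of 15 rose, 2 fell and 3 did not pass (10 and 3 adjusted over the list alone), median log2 change 1.07, adjusted p = 1.11e-05, or 0.0403 with an estimated correlation. TGF-beta and BMP response genes rose in 17 and fell in 3 of 22 cases, and 2 did not pass (17 and 3 adjusted over the list alone), median log2 change 0.46, adjusted p = 7.18e-05, or 0.0147 with an estimated correlation. Their median was 0.43 with genes absent from a group set to their bounds. Inhba and Fst rose by 2.18 and 2.24. The mitotic genes gave 20 increases, 2 decreases and 2 that did not pass of 24 (20 and 2 adjusted over the list alone), median log2 change 0.33, adjusted p = 1.05e-04, or 0.202 with an estimated correlation. For 28 tested E2F and DNA replication genes there were 18 increases and 5 decreases, and 5 did not pass (18 and 5 adjusted over the list alone), median log2 change 0.20, adjusted p = 0.0295, or 0.428 with an estimated correlation. Rrm2, needed to make nucleotides for replication, rose from 186 ± 4.29 to 469.9 ± 5.19 CPM. Of 17 Wnt pathway genes tested, 4 rose, 10 fell and 3 did not pass (4 and 10 adjusted over the list alone), median log2 change -0.61, adjusted p = 0.00166, or 0.0403 with an estimated correlation. Among the contractile and SRF target genes, 11 of 19 rose, 6 fell and 2 did not pass (11 and 6 adjusted over the list alone), median log2 change 0.29, adjusted p = 1.05e-04, or 0.202 with an estimated correlation. Erk-induced output genes rose in 9 and fell in 4 of 18 cases, and 5 did not pass (9 and 4 adjusted over the list alone), median log2 change 0.23, adjusted p = 0.0516, or 0.462 with an estimated correlation. Emp1 rose from 612 ± 10.8 to 1463 ± 29 CPM. The fibroblast markers gave 6 increases, 4 decreases and 1 that did not pass of 11 (6 and 4 adjusted over the list alone), median log2 change 0.18, mean -0.47, the test pointing down, adjusted p = 0.849, or 0.97 with an estimated correlation. Thy1 rose from 72.6 ± 3.4 to 182 ± 5.72 CPM and Prrx1 fell from 951 ± 6.18 to 492 ± 10.2 CPM. For 7 tested adipocyte markers there were 4 increases and 2 decreases, and 1 did not pass (4 and 2 adjusted over the list alone), median log2 change 2.45, adjusted p = 0.0313, or 0.202 with an estimated correlation. Pparg rose from 5.38 ± 0.827 to 32.8 ± 0.221 CPM. Of 14284 genes tested, 9630 passed, 4797 up and 4833 down, and 1923 of these changed by at least 2-fold.

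The same genotypes were compared after starvation, where the drive from serum is low. Dusp4 again was higher in CRE cells, 50.05 ± 1.25 against 5.42 ± 1.23 CPM, and so was Dusp5, 59.9 ± 2.49 against 23.2 ± 1.8 CPM. The chromatin gene Hmga2, an output of Ras signalling, was higher, 620.4 ± 21 against 282 ± 2.3 CPM, as were Emp1, 1397 ± 38.8 against 504 ± 11.9 CPM, and Serpine1, 240.4 ± 14.5 against 30.7 ± 0.615 CPM. Ptgs2, the inducible prostaglandin synthase, rose from 86.8 ± 5.08 to 519 ± 21.8 CPM and the YAP target Ccn1 from 207 ± 9.72 to 829.9 ± 34.5 CPM. Genes of the amino-acid stress response were lower in CRE cells. Trib3 measured 8.43 ± 0.362 against 42.1 ± 2.42 CPM, Ddit3 41.1 ± 1.18 against 140.2 ± 6.49 CPM and Atf5 65.2 ± 0.942 against 221 ± 6.23 CPM. The sterol enzyme genes Nsdhl and Acat2 were higher, log2 change 1.42 and 1.26. Fgf5 was 1250-fold lower, 95% counting interval 224 to 49500 and Igfbp5 fell (log2 -8.80). Of 23 Atf4 and amino-acid response genes tested, 3 rose, 19 fell and 1 did not pass (3 and 19 adjusted over the list alone), median log2 change -0.88, adjusted p = 7.33e-13, or 0.0201 with an estimated correlation. Among the cholesterol synthesis genes, 19 of 21 rose, 0 fell and 2 did not pass (19 and 0 adjusted over the list alone), median log2 change 0.47, adjusted p = 7.23e-08, or 0.0549 with an estimated correlation. Chemokines and cytokines rose in 11 and fell in 3 of 15 cases, and 1 did not pass (11 and 3 adjusted over the list alone), median log2 change 1.97, adjusted p = 1.57e-05, or 0.0549 with an estimated correlation. The E2F and DNA replication genes gave 23 increases, 4 decreases and 1 that did not pass of 28 (23 and 4 adjusted over the list alone), median log2 change 0.50, adjusted p = 1.24e-04, or 0.114 with an estimated correlation. For 18 tested Erk-induced output genes there were 12 increases and 4 decreases, and 2 did not pass (12 and 4 adjusted over the list alone), median log2 change 0.43, adjusted p = 0.00144, or 0.175 with an estimated correlation. Of 29 extracellular matrix genes tested, 18 rose, 9 fell and 2 did not pass (18 and 9 adjusted over the list alone), median log2 change 0.33, adjusted p = 0.00144, or 0.37 with an estimated correlation. Tnc rose by 3.05 and Postn fell (log2 -3.25). Among the neural crest and glial markers, 0 of 6 rose, 3 fell and 3 did not pass (0 and 3 adjusted over the list alone), median log2 change -0.52, adjusted p = 0.0129, or 0.074 with an estimated correlation. Fibroblast markers rose in 7 and fell in 4 of 11 cases, and 0 did not pass (7 and 4 adjusted over the list alone), median log2 change 0.23, mean -0.41, the test pointing up, adjusted p = 0.919, or 0.954 with an estimated correlation. Of 14284 genes, 9914 passed, 5121 up and 4793 down, and 2009 of these changed by at least 2-fold.

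With FGF present, the comparison asked what the missing feedback changes while the receptor is stimulated. Dusp4 was higher in CRE cells, 68.9 ± 1.13 against 11.3 ± 0.532 CPM, and the Ets factor gene Etv5, an FGF output, was lower, 55.8 ± 1.68 against 93.1 ± 0.615 CPM. Asns, which makes asparagine, fell from 221 ± 9.72 to 88.8 ± 3.5 CPM. Sema3e was 2310-fold higher, 95% counting interval 413 to 91100 and Tekt5 was at least 372-fold lower. The mesenchymal transition regulators and adhesion genes gave 11 increases, 3 decreases and 2 that did not pass of 16 (11 and 3 adjusted over the list alone), median log2 change 0.37, adjusted p = 1.87e-06, or 0.0386 with an estimated correlation. For 23 tested Atf4 and amino-acid response genes there were 1 increase and 17 decreases, and 5 did not pass (1 and 17 adjusted over the list alone), median log2 change -0.41, adjusted p = 1.88e-06, or 0.0678 with an estimated correlation. Of 22 matrix proteases and their inhibitors tested, 12 rose, 6 fell and 4 did not pass (12 and 6 adjusted over the list alone), median log2 change 0.52, adjusted p = 0.00114, or 0.112 with an estimated correlation. Among the Wnt pathway genes, 4 of 17 rose, 10 fell and 3 did not pass (4 and 10 adjusted over the list alone), median log2 change -0.47, adjusted p = 0.00114, or 0.0648 with an estimated correlation. Cholesterol synthesis genes rose in 13 and fell in 2 of 21 cases, and 6 did not pass (13 and 2 adjusted over the list alone), median log2 change 0.15, adjusted p = 0.00477, or 0.249 with an estimated correlation. The extracellular matrix genes gave 19 increases, 9 decreases and 1 that did not pass of 29 (19 and 9 adjusted over the list alone), median log2 change 0.45, adjusted p = 0.00114, or 0.445 with an estimated correlation. For 18 tested Erk-induced output genes there were 10 increases and 7 decreases, and 1 did not pass (10 and 7 adjusted over the list alone), median log2 change 0.18, adjusted p = 0.135, or 0.474 with an estimated correlation. Of 14284 genes, 9831 passed, 4927 up and 4904 down, and 1966 of these changed by at least 2-fold. In all 3 cultures together, 3480 genes were higher and 3330 lower in CRE cells, against 593 and 557 for independent lists, and 357 genes passed in all 3 with mixed signs. Pearson r of the log2 changes between the cultures, across genes that are not independent replicates, was 0.894 to 0.948.

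The response of VEC cells to FGF after starvation showed the stimulus with feedback intact. The Sprouty genes themselves rose, Spry1 from 21.8 ± 1.18 to 52.3 ± 2.11 CPM, Spry2 from 196 ± 8.85 to 336 ± 12.6 CPM and Spry4 from 18.9 ± 3.02 to 49.5 ± 3.71 CPM. The Erk phosphatase gene Dusp6 rose from 79.2 ± 4.51 to 286 ± 20.1 CPM, and the Egfr inhibitor gene Errfi1 from 198 ± 8.97 to 508 ± 17.4 CPM. The Ets factor gene Etv4 rose from 68.4 ± 4.74 to 168 ± 4.66 CPM, Ier3 from 16.2 ± 1.5 to 68.2 ± 4.61 CPM and Hmga2 from 282 ± 2.3 to 889.8 ± 25.2 CPM. The early factors Nr4a1 and Jun rose by 1.36 and 1.22. Ccl2 rose from 16.2 ± 0.774 to 207 ± 24.2 CPM, and the Egfr ligand gene Ereg from 15.2 ± 0.671 to 73.8 ± 4.82 CPM. The YAP target Ccn2 rose from 120 ± 0.835 to 522 ± 3.6 CPM. Ribosome assembly genes rose, such as Dkc1 from 45.6 ± 2.18 to 86.7 ± 2.6 CPM and Nop16 from 32.2 ± 1.95 to 56.1 ± 2.8 CPM. Fgfr2, a receptor for FGF, fell from 46.2 ± 2.59 to 21.5 ± 0.901 CPM. The inhibitor of differentiation Id2 fell (log2 -1.89). Of 18 Erk-induced output genes tested, 15 rose, 2 fell and 1 did not pass (16 and 2 adjusted over the list alone), median log2 change 0.77, adjusted p = 6.74e-33, or 4.96e-04 with an estimated correlation. Among the Erk feedback inhibitors, 8 of 12 rose, 2 fell and 2 did not pass (8 and 2 adjusted over the list alone), median log2 change 0.58, adjusted p = 1.1e-11, or 6.51e-04 with an estimated correlation. Myc and ribosome biogenesis genes rose in 24 and fell in 0 of 24 cases, and 0 did not pass (24 and 0 adjusted over the list alone), median log2 change 0.46, adjusted p = 3.38e-20, or 0.00607 with an estimated correlation. The chemokines and cytokines gave 10 increases, 1 decrease and 4 that did not pass of 15 (10 and 1 adjusted over the list alone), median log2 change 0.68, adjusted p = 3.37e-12, or 0.00423 with an estimated correlation. For 23 tested immediate-early genes there were 15 increases and 8 decreases, and 0 did not pass (15 and 8 adjusted over the list alone), median log2 change 0.35, adjusted p = 7.92e-04, or 0.183 with an estimated correlation. Of 23 Atf4 and amino-acid response genes tested, 1 rose, 15 fell and 7 did not pass (1 and 16 adjusted over the list alone), median log2 change -0.28, adjusted p = 1.41e-06, or 0.061 with an estimated correlation. Among the FoxO and growth-arrest genes, 5 of 19 rose, 9 fell and 5 did not pass (5 and 9 adjusted over the list alone), median log2 change -0.02, adjusted p = 0.0105, or 0.0798 with an estimated correlation. RNA quality and library markers rose in 0 and fell in 0 of 13 cases, and 13 did not pass (0 and 0 adjusted over the list alone), median log2 change -0.10, adjusted p = 0.721, or 0.826 with an estimated correlation. Of 14284 genes, 6836 passed, 3555 up and 3281 down, and 465 of these changed by at least 2-fold.

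The same stimulus was given to CRE cells to ask how they respond without the Sprouty genes. Dusp6 rose from 85.03 ± 2.52 to 153 ± 7.41 CPM and Errfi1 from 266 ± 8.53 to 479 ± 14.3 CPM. Mmp3 rose from 7.22 ± 0.587 to 40.8 ± 2.76 CPM, Sema7a, a guidance gene, from 25.96 ± 2.69 to 114 ± 2.15 CPM, and the Egfr ligand gene Hbegf from 178 ± 1.41 to 314 ± 8.81 CPM. Itgb3 rose from 21.1 ± 1.13 to 53.4 ± 0.979 CPM. The growth-arrest gene Gas1 fell from 428 ± 8.32 to 159.9 ± 6.71 CPM, the protease gene Adamts1 from 948 ± 21 to 404 ± 16.4 CPM and Klf4 from 84.2 ± 0.535 to 44.8 ± 1.7 CPM. The nuclear receptor genes Thrb, Vdr and Esr1 fell (log2 -1.90, -1.62 and -1.48). The Erk-induced output genes gave 16 increases, 0 decreases and 2 that did not pass of 18 (16 and 0 adjusted over the list alone), median log2 change 0.55, adjusted p = 1.19e-24, or 8.81e-04 with an estimated correlation. For 12 tested Erk feedback inhibitors there were 10 increases and 0 decreases, and 2 did not pass (10 and 0 adjusted over the list alone), median log2 change 0.48, adjusted p = 7.13e-14, or 4.29e-04 with an estimated correlation. Of 24 Myc and ribosome biogenesis genes tested, 19 rose, 0 fell and 5 did not pass (19 and 0 adjusted over the list alone), median log2 change 0.29, adjusted p = 4.44e-11, or 0.0225 with an estimated correlation. Among the E2F and DNA replication genes, 0 of 28 rose, 25 fell and 3 did not pass (0 and 26 adjusted over the list alone), median log2 change -0.29, adjusted p = 2.06e-08, or 0.0203 with an estimated correlation. P53 target genes rose in 0 and fell in 17 of 22 cases, and 5 did not pass (0 and 17 adjusted over the list alone), median log2 change -0.26, adjusted p = 1.37e-07, or 0.00342 with an estimated correlation. The interferon-stimulated genes gave 0 increases, 15 decreases and 9 that did not pass of 24 (0 and 16 adjusted over the list alone), median log2 change -0.44, adjusted p = 2.53e-04, or 0.0112 with an estimated correlation. For 7 tested cartilage and bone markers there were 3 increases and 1 decrease, and 3 did not pass (3 and 1 adjusted over the list alone), median log2 change 0.34, adjusted p = 0.0139, or 0.0799 with an estimated correlation. Of 21 EGF family ligands and other growth factors tested, 10 rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone), median log2 change 0.33, adjusted p = 7.81e-05, or 0.0142 with an estimated correlation. Of 14284 genes, 6432 passed, 3155 up and 3277 down, and 320 of these changed by at least 2-fold.

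A direct test of the difference between the responses to FGF, CRE minus VEC, asked where Sprouty loss alters the response. Dusp6 rose less in CRE cells, a difference of -1.01 log2 units, and so did Ier3, -1.21, Hmga2, -0.95, and Ccl2, -2.35. The cyclin gene Ccnd1 differed by -0.80 and Ccn2 by -1.32. Sox4 fell less in CRE cells, 1.32, and Trib3 differed by 1.16. Among 21 cholesterol synthesis genes, the response was higher in CRE cells for 0 and lower for 16, and 5 did not pass (0 and 16 adjusted over the list alone), median log2 difference -0.28, adjusted p = 7.63e-17, or 0.00918 with an estimated correlation. E2F and DNA replication genes responded higher in CRE cells in 0 and lower in 19 of 28 cases, and 9 did not pass (0 and 22 adjusted over the list alone), median log2 difference -0.30, adjusted p = 1.26e-12, or 0.0105 with an estimated correlation. Of 23 Atf4 and amino-acid response genes, 12 had a positive difference, 1 a negative one and 10 did not pass (13 and 2 adjusted over the list alone), median log2 difference 0.26, adjusted p = 1.26e-12, or 0.00933 with an estimated correlation. Among 15 chemokines and cytokines, the response was higher in CRE cells for 0 and lower for 5, and 10 did not pass (0 and 6 adjusted over the list alone), median log2 difference -0.45, adjusted p = 1.53e-10, or 0.00933 with an estimated correlation. Of 18 Erk-induced output genes, 4 had a positive difference, 10 a negative one and 4 did not pass (4 and 10 adjusted over the list alone), median log2 difference -0.32, adjusted p = 2.77e-09, or 0.023 with an estimated correlation. Among 12 Erk feedback inhibitors, the response was higher in CRE cells for 2 and lower for 3, and 7 did not pass (2 and 4 adjusted over the list alone), median log2 difference -0.05, adjusted p = 0.169, or 0.34 with an estimated correlation. Cartilage and bone markers responded higher in CRE cells in 1 and lower in 0 of 7 cases, and 6 did not pass (2 and 0 adjusted over the list alone), median log2 difference 0.12, adjusted p = 4.86e-04, or 0.0311 with an estimated correlation. Of 14284 genes, 1791 passed, 796 up and 995 down, and 79 of these changed by at least 2-fold. Fitted with only the groups compared, the majority turned, with 997 up and 729 down. In both genotypes 2347 genes rose and 2130 fell with FGF, against 785 and 753 for independent lists, and 163 changed in opposite directions. This count was chosen after the data were seen. Pearson r of the responses across genes was 0.604.

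Starved and growing VEC cells were compared to describe the withdrawal of serum. Genes for cell division fell, among them the cyclin gene Ccne1 from 54.8 ± 1.77 to 12.04 ± 0.341 CPM, the helicase gene Mcm5 from 369.6 ± 20.9 to 104 ± 3.28 CPM, the checkpoint gene Bub1b from 142 ± 2.96 to 45.05 ± 0.769 CPM and Birc5 from 143 ± 0.952 to 46.3 ± 0.253 CPM. Ribosome assembly genes fell, such as Dkc1 from 133 ± 3.23 to 45.6 ± 2.18 CPM. Outputs of Erk fell, with Fosl1 from 28.6 ± 2.15 to 9.71 ± 0.803 CPM, Hmga2 from 938 ± 10.6 to 282 ± 2.3 CPM and Mmp3 from 86.7 ± 5.66 to 3.67 ± 0.353 CPM. The collagen genes Col3a1 and Col1a1 rose from 77.5 ± 1.78 to 4210 ± 95.1 CPM and from 1582 ± 166 to 3858 ± 396 CPM. The arrest genes Gadd45a and Gas1 rose by 2.38 and 1.91. Sterol synthesis genes rose, with Fdps from 22.5 ± 0.896 to 71.6 ± 3.39 CPM and Insig1 from 48.99 ± 4.13 to 147 ± 4.5 CPM. The stress genes Ddit3 and Trib3 rose by 1.58 and 1.55. Apod rose by 6.58, and Id4 fell (log2 -3.51). The E2F and DNA replication genes gave 0 increases, 28 decreases and 0 that did not pass of 28 (0 and 28 adjusted over the list alone), median log2 change -1.59, adjusted p = 5.74e-46, or 1.1e-04 with an estimated correlation. For 24 tested mitotic genes there were 0 increases and 24 decreases, and 0 did not pass (0 and 24 adjusted over the list alone), median log2 change -1.27, adjusted p = 2.31e-33, or 7.34e-04 with an estimated correlation. Of 24 Myc and ribosome biogenesis genes tested, 0 rose, 24 fell and 0 did not pass (0 and 24 adjusted over the list alone), median log2 change -0.90, adjusted p = 2.14e-19, or 0.00698 with an estimated correlation. Among the cholesterol synthesis genes, 20 of 21 rose, 0 fell and 1 did not pass (21 and 0 adjusted over the list alone), median log2 change 1.06, adjusted p = 1.31e-19, or 0.00198 with an estimated correlation. Extracellular matrix genes rose in 22 and fell in 4 of 29 cases, and 3 did not pass (22 and 4 adjusted over the list alone), median log2 change 1.01, adjusted p = 1.38e-13, or 0.0434 with an estimated correlation. The Erk-induced output genes gave 4 increases, 13 decreases and 1 that did not pass of 18 (4 and 13 adjusted over the list alone), median log2 change -0.87, adjusted p = 1.62e-08, or 0.0243 with an estimated correlation. For 19 tested FoxO and growth-arrest genes there were 13 increases and 6 decreases, and 0 did not pass (13 and 6 adjusted over the list alone), median log2 change 0.50, adjusted p = 1.94e-04, or 0.0198 with an estimated correlation. Of 23 Atf4 and amino-acid response genes tested, 14 rose, 6 fell and 3 did not pass (15 and 6 adjusted over the list alone), median log2 change 0.34, adjusted p = 0.0148, or 0.246 with an estimated correlation. Among the RNA quality and library markers, 5 of 13 rose, 2 fell and 6 did not pass (5 and 2 adjusted over the list alone), median log2 change 0.23, adjusted p = 0.588, or 0.709 with an estimated correlation. Fibroblast markers rose in 7 and fell in 3 of 11 cases, and 1 did not pass (7 and 3 adjusted over the list alone), median log2 change 0.34, adjusted p = 0.0376, or 0.182 with an estimated correlation. Of 14284 genes, 9983 passed, 4971 up and 5012 down, and 2198 of these changed by at least 2-fold.

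In CRE cells the same withdrawal of serum was compared to ask whether it acts alike without Sprouty. Ccne1 fell from 64.6 ± 1.42 to 22.6 ± 1.03 CPM, Rrm2 from 469.9 ± 5.19 to 146 ± 1.55 CPM and the cyclin gene Ccna2 from 269 ± 6.14 to 100.2 ± 4.61 CPM. Fdps rose from 30.4 ± 1.39 to 134 ± 2.78 CPM and Nsdhl from 38.4 ± 0.708 to 167 ± 5.65 CPM. Col3a1 rose from 62.1 ± 6.31 to 2511 ± 26.8 CPM and the matrix gene Dpt from 2.25 ± 0.305 to 67.5 ± 1.01 CPM. The folate enzyme gene Shmt2 fell from 371 ± 9.9 to 138 ± 3.17 CPM, Mthfd2 from 154 ± 7.4 to 57.9 ± 0.547 CPM, Psat1 from 707 ± 14.4 to 278 ± 7.31 CPM and Asns from 179.6 ± 2.32 to 71.5 ± 4.58 CPM. Mest rose by 4.68 and Igf2 by 2.19. Id4 fell (log2 -3.60), as did Mmp13 (log2 -4.90). The cholesterol synthesis genes gave 21 increases, 0 decreases and 0 that did not pass of 21 (21 and 0 adjusted over the list alone), median log2 change 1.53, adjusted p = 1.2e-50, or 4.06e-05 with an estimated correlation. For 28 tested E2F and DNA replication genes there were 0 increases and 28 decreases, and 0 did not pass (0 and 28 adjusted over the list alone), median log2 change -1.32, adjusted p = 3.52e-40, or 1.14e-04 with an estimated correlation. Of 24 mitotic genes tested, 0 rose, 24 fell and 0 did not pass (0 and 24 adjusted over the list alone), median log2 change -1.26, adjusted p = 3.1e-37, or 3.32e-04 with an estimated correlation. Among the imprinted growth genes, 12 of 14 rose, 0 fell and 2 did not pass (12 and 0 adjusted over the list alone), median log2 change 0.89, adjusted p = 8.32e-11, or 1.14e-04 with an estimated correlation. Atf4 and amino-acid response genes rose in 5 and fell in 16 of 23 cases, and 2 did not pass (5 and 16 adjusted over the list alone), median log2 change -0.47, adjusted p = 1.74e-04, or 0.0789 with an estimated correlation. The autophagy and lysosome genes gave 18 increases, 2 decreases and 2 that did not pass of 22 (18 and 2 adjusted over the list alone), median log2 change 0.54, adjusted p = 6.28e-06, or 0.0394 with an estimated correlation. For 17 tested receptor tyrosine kinases there were 12 increases and 4 decreases, and 1 did not pass (12 and 4 adjusted over the list alone), median log2 change 0.33, adjusted p = 0.0396, or 0.347 with an estimated correlation. Of 7 cartilage and bone markers tested, 0 rose, 4 fell and 3 did not pass (0 and 4 adjusted over the list alone), median log2 change -0.67, adjusted p = 0.0447, or 0.138 with an estimated correlation. Among the fibroblast markers, 6 of 11 rose, 4 fell and 1 did not pass (6 and 4 adjusted over the list alone), median log2 change 0.73, adjusted p = 0.0036, or 0.0571 with an estimated correlation. Of 14284 genes, 10103 passed, 5127 up and 4976 down, and 1986 of these changed by at least 2-fold.

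The difference between the responses to starvation, CRE minus VEC, was tested directly. Trib3, a stress kinase homologue, measured 14.4 ± 0.999 CPM in growing and 42.1 ± 2.42 CPM in starved VEC cells, and 16.1 ± 0.0344 and 8.43 ± 0.362 CPM in CRE cells, a difference of -2.48 log2 units. In the same list, Mthfd2 differed by -1.50 and Atf5 by -1.31. The sterol enzyme gene Acat2 rose more in CRE cells, 1.11, as did Lss, 0.81. The early factors Egr3 and Myc differed by 1.63 and 0.99, and Dusp6 differed by 1.12. Atf4 and amino-acid response genes responded higher in CRE cells in 1 and lower in 21 of 23 cases, and 1 did not pass (1 and 21 adjusted over the list alone), median log2 difference -0.74, adjusted p = 2.4e-40, or 8.46e-05 with an estimated correlation. Of 21 cholesterol synthesis genes, 20 had a positive difference, 0 a negative one and 1 did not pass (20 and 0 adjusted over the list alone), median log2 difference 0.55, adjusted p = 1.21e-22, or 0.00128 with an estimated correlation. Among 23 immediate-early genes, the response was higher in CRE cells for 14 and lower for 4, and 5 did not pass (15 and 4 adjusted over the list alone), median log2 difference 0.30, adjusted p = 4.72e-07, or 0.0977 with an estimated correlation. Of 28 E2F and DNA replication genes, 17 had a positive difference, 0 a negative one and 11 did not pass (17 and 0 adjusted over the list alone), median log2 difference 0.30, adjusted p = 2.06e-05, or 0.0977 with an estimated correlation. Among 12 Erk feedback inhibitors, the response was higher in CRE cells for 5 and lower for 2, and 5 did not pass (6 and 3 adjusted over the list alone), median log2 difference 0.12, adjusted p = 1.68e-04, or 0.0293 with an estimated correlation. Erk-induced output genes responded higher in CRE cells in 10 and lower in 4 of 18 cases, and 4 did not pass (11 and 4 adjusted over the list alone), median log2 difference 0.18, adjusted p = 0.0129, or 0.27 with an estimated correlation. Of 11 fibroblast markers, 5 had a positive difference, 0 a negative one and 6 did not pass (5 and 0 adjusted over the list alone), median log2 difference 0.12, adjusted p = 0.0129, or 0.149 with an estimated correlation. Among 6 neural crest and glial markers, the response was higher in CRE cells for 0 and lower for 2, and 4 did not pass (0 and 2 adjusted over the list alone), median log2 difference -0.09, adjusted p = 0.023, or 0.0977 with an estimated correlation. Of 14284 genes, 4432 passed, 2516 up and 1916 down, and 434 of these changed by at least 2-fold. With library totals as the scaling, added after the data were seen, the share of increases among the genes that passed was 43.82% against 56.77%. In both genotypes 3860 genes rose and 4032 fell on starvation, against 1784 and 1746 for independent lists, and 411 changed in opposite directions. This count was also chosen after the data were seen. Pearson r across genes was 0.776.

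**Figure D2:**
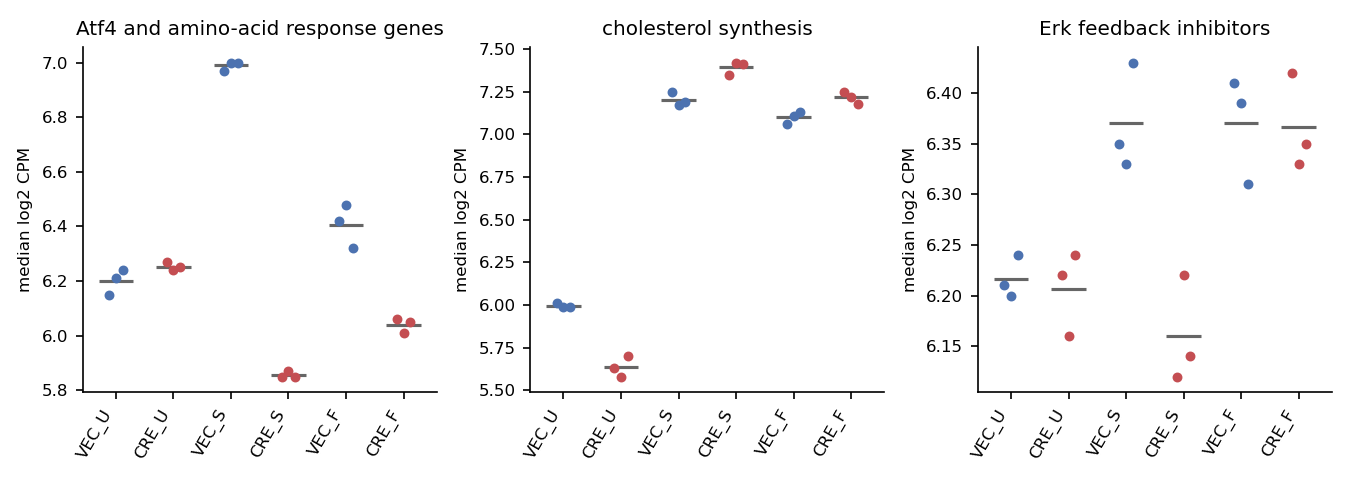
Median log2 CPM of the members of 3 gene lists (Atf4 and amino-acid response, cholesterol synthesis, Erk feedback inhibitors) in each of the 18 untransduced libraries, with points for libraries and bars for the group mean. The Atf4 medians are 6.97 to 7 in starved VEC and 5.85 to 5.87 in starved CRE libraries.

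VEC cells with KRas G12V were compared with VEC cells with the empty vector to ask what an active oncogene changes when Sprouty is intact. Kras itself measured 173 ± 16.7 against 161 ± 17.5 CPM and did not pass. Whether reads from a construct count toward the mouse gene is not known, here and for Hras and Braf. The Erk feedback gene Dusp6 rose from 113 ± 10.9 to 384 ± 39.8 CPM, as did Spry4 from 7.39 ± 0.264 to 25.9 ± 1.21 CPM, Spry2 from 102 ± 8.18 to 157 ± 12.2 CPM and Spred1 from 132 ± 5.19 to 294 ± 53 CPM. The receptor genes Egfr and Flt1 fell from 89.4 ± 23.2 to 28.7 ± 3.5 CPM and from 102 ± 15.2 to 34.1 ± 7.06 CPM, while Fgfr1 rose from 91.96 ± 8.23 to 176 ± 46 CPM. The matrix protease genes Mmp3 and Mmp10 rose from 14.7 ± 3.67 to 1425 ± 572 CPM and from 4.91 ± 0.498 to 162 ± 73.8 CPM. Spp1, which encodes osteopontin, rose from 178 ± 29.1 to 1534 ± 651 CPM, and Bmp2 from 4.15 ± 2.3 to 59.7 ± 20.4 CPM. The YAP target gene Amotl2 fell from 304 ± 45.2 to 113 ± 47.3 CPM. The lysosomal protease genes Ctsl and Ctsb rose from 699 ± 46.1 to 2393 ± 555 CPM and from 907 ± 86.6 to 2684 ± 203 CPM. The interferon-response gene Usp18 rose from 0.169 ± 0.0126 to 8.23 ± 6.44 CPM. Of the largest changes, Il1rn, an inhibitor of interleukin 1, rose by 7.09, Crisp1 by 8.44 and Prokr2 was 757-fold higher, 95% counting interval 136 to 30000. Nog, an inhibitor of BMP signals, fell (log2 -3.65), as did Arhgap36 (log2 -3.32). Of 12 Erk feedback inhibitors tested, 7 rose, 0 fell and 5 did not pass (8 and 0 adjusted over the list alone), median log2 change 0.64, adjusted p = 3.08e-04, or 0.251 with an estimated correlation. Among the Myc and ribosome biogenesis genes, 0 of 24 rose, 20 fell and 4 did not pass (0 and 22 adjusted over the list alone), median log2 change -0.44, adjusted p = 8.81e-10, or 0.254 with an estimated correlation. Interferon-stimulated genes rose in 24 and fell in 1 of 29 cases, and 4 did not pass (25 and 1 adjusted over the list alone), median log2 change 2.27, adjusted p = 2.32e-09, or 0.345 with an estimated correlation. The cholesterol synthesis genes gave 0 increases, 15 decreases and 6 that did not pass of 21 (0 and 20 adjusted over the list alone), median log2 change -0.54, adjusted p = 3.39e-08, or 0.345 with an estimated correlation. For 28 tested E2F and DNA replication genes there were 0 increases and 13 decreases, and 15 did not pass (0 and 13 adjusted over the list alone), median log2 change -0.27, adjusted p = 2.03e-06, or 0.37 with an estimated correlation. Of 22 autophagy and lysosome genes tested, 14 rose, 0 fell and 8 did not pass (14 and 0 adjusted over the list alone), median log2 change 0.51, adjusted p = 1.07e-06, or 0.251 with an estimated correlation. Among the contractile and SRF target genes, 0 of 19 rose, 12 fell and 7 did not pass (0 and 12 adjusted over the list alone), median log2 change -0.54, adjusted p = 2.17e-08, or 0.251 with an estimated correlation. Cartilage and bone markers rose in 4 and fell in 0 of 5 cases, and 1 did not pass (4 and 0 adjusted over the list alone), median log2 change 1.45, adjusted p = 0.00211, or 0.251 with an estimated correlation. The fibroblast markers gave 3 increases, 3 decreases and 6 that did not pass of 12 (3 and 3 adjusted over the list alone), median log2 change 0.18, adjusted p = 0.615, or 0.808 with an estimated correlation. Of 13927 genes tested, 3991 passed, 2279 up and 1712 down, and 1133 of these changed by at least 2-fold. Fitted with only the 6 libraries compared, 2533 passed. With library totals as the scaling, 67.97% of the genes that passed were increases, against 57.1%.

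The same question was asked of HRas G12V. Counts of mouse Hras were 67.5 ± 1.53 against 81.7 ± 3.63 CPM, with the same doubt about construct reads, and Spry1 fell from 4.74 ± 0.653 to 2.09 ± 0.513 CPM. Spry4 rose from 7.39 ± 0.264 to 43.1 ± 9.12 CPM, Dusp6 from 113 ± 10.9 to 415 ± 67 CPM and Spred3 from 21.4 ± 3.52 to 46.4 ± 4.24 CPM. The ligand genes Btc and Areg rose from 0.259 ± 0.117 to 7.65 ± 1.18 CPM and from 2.26 ± 0.181 to 11.8 ± 1.66 CPM. Egfr fell from 89.4 ± 23.2 to 19.6 ± 2.76 CPM and Epha7 from 16.04 ± 4.22 to 1.74 ± 0.323 CPM. Mmp3 rose from 14.7 ± 3.67 to 2285 ± 452 CPM, Il33 from 0.155 ± 0.0756 to 19.5 ± 4.31 CPM, and Itgb3 from 0.353 ± 0.071 to 17.8 ± 7.32 CPM. Acta2 fell from 75.3 ± 20.1 to 7.06 ± 0.996 CPM, Ccn2 from 245 ± 61.9 to 29.8 ± 19.6 CPM and Serpine1 from 308 ± 111 to 25.3 ± 9.14 CPM. Thy1, a fibroblast surface gene, fell from 35.1 ± 1.17 to 7.75 ± 1.39 CPM, and Dcn rose from 73.4 ± 28.5 to 1941 ± 253 CPM. The stress gene Gadd45b fell (log2 -2.55), as did Rrm1 (log2 -0.88). Igsf5 was at least 183-fold higher and Arhgap36 fell (log2 -5.81). For 12 tested Erk feedback inhibitors there were 10 increases and 0 decreases, and 2 did not pass (10 and 0 adjusted over the list alone), median log2 change 0.98, adjusted p = 6.26e-06, or 0.259 with an estimated correlation. Of 18 Erk-induced output genes tested, 10 rose, 3 fell and 5 did not pass (10 and 4 adjusted over the list alone), median log2 change 0.43, adjusted p = 0.0105, or 0.399 with an estimated correlation. Among the Myc and ribosome biogenesis genes, 0 of 24 rose, 21 fell and 3 did not pass (0 and 23 adjusted over the list alone), median log2 change -0.50, adjusted p = 1.81e-08, or 0.324 with an estimated correlation. E2F and DNA replication genes rose in 1 and fell in 21 of 28 cases, and 6 did not pass (1 and 22 adjusted over the list alone), median log2 change -0.42, adjusted p = 2.56e-07, or 0.372 with an estimated correlation. The mitotic genes gave 0 increases, 16 decreases and 8 that did not pass of 24 (0 and 20 adjusted over the list alone), median log2 change -0.44, adjusted p = 3.42e-05, or 0.439 with an estimated correlation. For 16 tested YAP/TEAD target genes there were 3 increases and 10 decreases, and 3 did not pass (3 and 10 adjusted over the list alone), median log2 change -0.63, adjusted p = 9.42e-04, or 0.372 with an estimated correlation. Of 5 cartilage and bone markers tested, 5 rose, 0 fell and 0 did not pass (5 and 0 adjusted over the list alone), median log2 change 1.44, adjusted p = 0.00181, or 0.259 with an estimated correlation. Among the interferon-stimulated genes, 22 of 29 rose, 1 fell and 6 did not pass (23 and 1 adjusted over the list alone), median log2 change 2.14, adjusted p = 6.26e-06, or 0.439 with an estimated correlation. Receptor tyrosine kinases rose in 4 and fell in 7 of 17 cases, and 6 did not pass (4 and 7 adjusted over the list alone), median log2 change -0.10, adjusted p = 0.0525, or 0.439 with an estimated correlation. With replicate number as a block, the last of these had adjusted p = 0.037. Of 13927 genes, 5846 passed, 3148 up and 2698 down, and 1711 of these changed by at least 2-fold.

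BRaf V600E, which signals from below Ras, was compared with the empty vector in the same way. Braf rose from 51.5 ± 2.69 to 108 ± 20.4 CPM. Dusp6 rose from 113 ± 10.9 to 452 ± 81.4 CPM, Spry4 from 7.39 ± 0.264 to 37.4 ± 15.6 CPM and Egr3 from 5.88 ± 2.93 to 25.6 ± 10.9 CPM. The ligand genes Btc and Areg rose from 0.259 ± 0.117 to 12.8 ± 7.99 CPM and from 2.26 ± 0.181 to 18.9 ± 10.5 CPM, and Fgf5 fell from 11.2 ± 2.04 to 0.925 ± 0.188 CPM. Mmp3 rose from 14.7 ± 3.67 to 474 ± 224 CPM and Itgb3 from 0.353 ± 0.071 to 25.4 ± 15.2 CPM. Tagln fell from 81.6 ± 20.9 to 24.7 ± 5.66 CPM and Postn from 108 ± 53.1 to 31.5 ± 5.3 CPM. Rgs5 was 390-fold higher, 95% counting interval 133 to 1900, and Igsf1 and Xirp2 fell (log2 -3.54 and -3.99). The Erk feedback inhibitors gave 8 increases, 0 decreases and 4 that did not pass of 12 (9 and 0 adjusted over the list alone), median log2 change 0.82, adjusted p = 6.58e-06, or 0.232 with an estimated correlation. For 18 tested Erk-induced output genes there were 6 increases and 2 decreases, and 10 did not pass (6 and 2 adjusted over the list alone), median log2 change 0.19, adjusted p = 0.0028, or 0.33 with an estimated correlation. Of 22 autophagy and lysosome genes tested, 13 rose, 0 fell and 9 did not pass (14 and 0 adjusted over the list alone), median log2 change 0.42, adjusted p = 3.8e-06, or 0.232 with an estimated correlation. Among the Myc and ribosome biogenesis genes, 1 of 24 rose, 15 fell and 8 did not pass (1 and 21 adjusted over the list alone), median log2 change -0.34, adjusted p = 6.89e-07, or 0.269 with an estimated correlation. Extracellular matrix genes rose in 2 and fell in 14 of 29 cases, and 13 did not pass (3 and 16 adjusted over the list alone), median log2 change -0.42, adjusted p = 6.58e-06, or 0.232 with an estimated correlation. The chemokines and cytokines gave 6 increases, 0 decreases and 7 that did not pass of 13 (6 and 1 adjusted over the list alone), median log2 change 0.56, adjusted p = 0.0028, or 0.232 with an estimated correlation. For 5 tested cartilage and bone markers there were 3 increases and 0 decreases, and 2 did not pass (3 and 0 adjusted over the list alone), median log2 change 0.93, adjusted p = 0.0113, or 0.232 with an estimated correlation. Of 29 interferon-stimulated genes tested, 7 rose, 0 fell and 22 did not pass (11 and 1 adjusted over the list alone), median log2 change 1.17, adjusted p = 0.00179, or 0.527 with an estimated correlation. With replicate number as a block, 16 of these rose and 1 fell, adjusted p = 0.00371, or 0.531 with an estimated correlation. Among the EGF family ligands and other growth factors, 7 of 18 rose, 2 fell and 9 did not pass (7 and 2 adjusted over the list alone), median log2 change 0.19, adjusted p = 0.0157, or 0.385 with an estimated correlation. Of 13927 genes, 3287 passed, 1862 up and 1425 down, and 935 of these changed by at least 2-fold. With the block, 5122 passed, 5179 with the block and only the 6 libraries compared, and 2142 without VEC_EV replicate 3. The block also gave adjusted p = 0.0434 for a lower Atf4 list, against 0.0674, and 0.0337 for higher mesenchymal and adhesion genes, against 0.0608. With library totals as the scaling, 67.84% of the genes that passed were increases, against 56.65%.

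**Figure D3:**
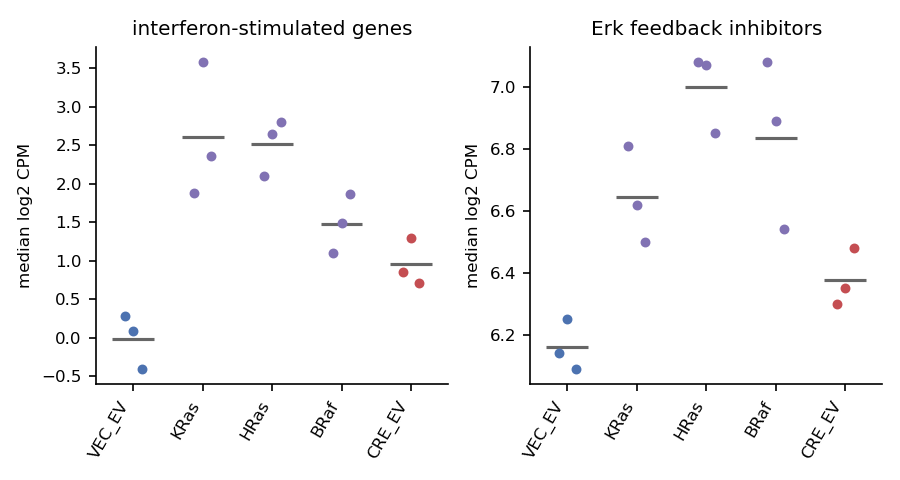
Median log2 CPM of the members of 2 gene lists (interferon-stimulated genes, Erk feedback inhibitors) in each of the 15 transduced libraries, with points for libraries and bars for the group mean. The interferon-stimulated medians are 1.10 to 3.58 in the 9 oncogene libraries, -0.40 to 0.28 in VEC_EV and 0.72 to 1.30 in CRE_EV.

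Growing CRE and VEC cells were compared again, with the empty vector and puromycin. Dusp4 rose from 20.1 ± 4.03 to 65.1 ± 12 CPM and Spred1 from 132 ± 5.19 to 294 ± 14.7 CPM. The ephrin receptor gene Epha4 rose from 8.81 ± 0.175 to 50.2 ± 6.66 CPM, Emp1 from 575 ± 22.2 to 1451 ± 153 CPM and Mmp3 from 14.7 ± 3.67 to 49.3 ± 11.9 CPM. Tgfa rose from 2.23 ± 0.625 to 18.3 ± 1.55 CPM, Ccl2 from 9.94 ± 3.02 to 175 ± 12.6 CPM and Acta2 from 75.3 ± 20.1 to 876 ± 12.4 CPM. The adipogenic factor Pparg rose from 4.38 ± 0.357 to 39.9 ± 1.44 CPM. Dlk1 rose from 0.406 ± 0.321 to 393 ± 107 CPM, Ndn was at least 189-fold higher and Chst2 was at least 382-fold higher. Fgf5 was 766-fold lower, 95% counting interval 137 to 30300, and Tekt5 fell (log2 -7.81). Matrix proteases and their inhibitors rose in 16 and fell in 0 of 21 cases, and 5 did not pass (17 and 0 adjusted over the list alone), median log2 change 1.25, adjusted p = 2.82e-05, or 0.0764 with an estimated correlation. The adipocyte markers gave 4 increases, 1 decrease and 1 that did not pass of 6 (4 and 1 adjusted over the list alone), median log2 change 3.31, adjusted p = 2.82e-05, or 0.0192 with an estimated correlation. For 17 tested mesenchymal transition regulators and adhesion genes there were 11 increases and 2 decreases, and 4 did not pass (11 and 2 adjusted over the list alone), median log2 change 0.84, adjusted p = 9.16e-05, or 0.288 with an estimated correlation. Of 21 TGF-beta and BMP response genes tested, 16 rose, 1 fell and 4 did not pass (16 and 1 adjusted over the list alone), median log2 change 0.79, adjusted p = 1.86e-04, or 0.47 with an estimated correlation. Among the chemokines and cytokines, 9 of 13 rose, 2 fell and 2 did not pass (9 and 3 adjusted over the list alone), median log2 change 1.59, adjusted p = 2.96e-04, or 0.155 with an estimated correlation. Myc and ribosome biogenesis genes rose in 0 and fell in 20 of 24 cases, and 4 did not pass (0 and 22 adjusted over the list alone), median log2 change -0.48, adjusted p = 1.62e-06, or 0.479 with an estimated correlation. The Erk-induced output genes gave 8 increases, 2 decreases and 8 that did not pass of 18 (8 and 2 adjusted over the list alone), median log2 change 0.29, adjusted p = 0.0347, or 0.597 with an estimated correlation. For 18 tested EGF family ligands and other growth factors there were 10 increases and 2 decreases, and 6 did not pass (10 and 2 adjusted over the list alone), median log2 change 0.49, adjusted p = 0.0468, or 0.597 with an estimated correlation. With the replicate block, the last of these had adjusted p = 0.0903. Of 12 fibroblast markers tested, 6 rose, 3 fell and 3 did not pass (6 and 3 adjusted over the list alone), median log2 change 0.28, mean -0.14, the test pointing up, adjusted p = 0.378, or 0.847 with an estimated correlation. Of 13927 genes, 6935 passed, 3738 up and 3197 down, and 2000 of these changed by at least 2-fold. In both experiments, 2877 genes were higher and 2525 lower in CRE cells, against 1260 and 1109 for independent lists, and 292 had opposite signs. Pearson r across genes was 0.881. Both experiments may have used the same cells and need not be independent.

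The 3 oncogenes were then compared with each other through the genes they shared. All 3 raised 1405 genes and lowered 1032, against 69 and 34 for independent lists, and 4 genes passed in all 3 with mixed signs. The covariance of the log2 changes was 0.903 for KRas and HRas, 0.659 for KRas and BRaf and 0.795 for HRas and BRaf. In 20 simulated sets the medians were 0.047, 0.0473 and 0.047. There all groups, VEC_EV included, were drawn without change from the VEC_EV means, with genes and libraries varying independently. The simulated values therefore lack the pairing by replicate number and any deviation particular to the real VEC_EV libraries. Pearson r across genes was 0.946, 0.885 and 0.866. With CRE_EV as well, 762 genes were higher and 547 lower in all 4, against 18 and 8 for independent lists, and 279 had mixed signs. The covariances of KRas, HRas and BRaf with CRE_EV were 0.37, 0.447 and 0.332, against simulated medians of 0.047, 0.0469 and 0.0469. Their r was 0.336, 0.329 and 0.313. Simulated median r, 0.474 to 0.495, came from the common control alone and is no benchmark. Of 12 Erk feedback inhibitors, 6 rose with all 3 oncogenes and 0 fell, and of 18 Erk-induced output genes 5 rose and 2 fell. Of 28 E2F and replication genes 9 fell with all 3 and 0 rose, as did 9 of 21 cholesterol synthesis genes. The shared count of the 3 oncogenes was 3796 with the replicate block and 1591 without VEC_EV replicate 3, and that with CRE_EV was 2136 and 802. With library totals as the scaling, increases made up 69% and 69.83% of these 2 counts, against 57.65% and 58.21%.

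The oncogenes were also compared directly, to ask whether the 2 Ras proteins and BRaf differ. KRas against HRas gave 153 genes, 70 higher and 83 lower with KRas. Arhgap36 was higher with KRas, 83.2 ± 35.1 against 14.8 ± 5.73 CPM, while Prune2 was lower, 1.09 ± 0.46 against 6.43 ± 1.36 CPM. The count was 1097 with the replicate block, 1087 with the block and only the 6 libraries compared, 36 with only those libraries and 449 by DESeq2. Without HRas replicate 1, 2 or 3 it was 59, 17 or 75, and without KRas replicate 1, 2 or 3 it was 846, 93 or 31. The majority turned to increases without HRas replicate 3 (39 and 36), KRas replicate 2 (55 and 38) or KRas replicate 3 (18 and 13). BRaf against HRas gave 1504 genes, 644 higher and 860 lower with BRaf. Cemip, which breaks down hyaluronan, was higher with BRaf, 22.9 ± 10.6 against 2.32 ± 0.421 CPM, and Lum, 2.72 ± 1.22 against 52.2 ± 8.14 CPM, and Mmp12, 1.76 ± 0.941 against 26.2 ± 8.55 CPM, were lower. This count was 3213 with the block and 4311 with the block and only the 6 libraries compared. It was 935 without BRaf replicate 2, 834 without BRaf replicate 3, 915 without HRas replicate 1 and 794 without HRas replicate 2. BRaf against KRas gave 197 genes, 97 higher and 100 lower with BRaf. Trpm5 was higher with BRaf, 5.39 ± 2.47 against 1.07 ± 0.263 CPM, and Lum was lower, 2.72 ± 1.22 against 35.1 ± 20.6 CPM. This count was 666 with the block, 479 with the block and only the 6 libraries compared, and 348 by DESeq2. In edgeR with only the 6 libraries it was 0, with 872 genes at an unadjusted p under 0.05. It was 131 without BRaf replicate 1, 54 without BRaf replicate 2, and 105, 94 and 320 without KRas replicate 1, 2 and 3. Without BRaf replicate 3, 116 were higher and 62 lower.

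Oncogene and CRE_EV cells were also compared. Against CRE_EV, KRas gave 6510 genes, 3262 higher and 3248 lower. Lum was 1250-fold higher, 95% counting interval 345 to 10300, Igfbp5 rose by 9.05, and Dlk1 fell from 393 ± 107 to 0.280 ± 0.286 CPM. HRas gave 6880, 3444 higher and 3436 lower, and Crisp1 rose from 0.340 ± 0.301 to 524 ± 74.9 CPM and Auts2 at least 548-fold lower. BRaf gave 6655, 3291 higher and 3364 lower, and Myo18b rose from 0.117 ± 0.028 to 36.1 ± 12.9 CPM and Gnai1 at least 209-fold lower. These comparisons also hold the difference in genotype between the cells.

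**Figure D4:**
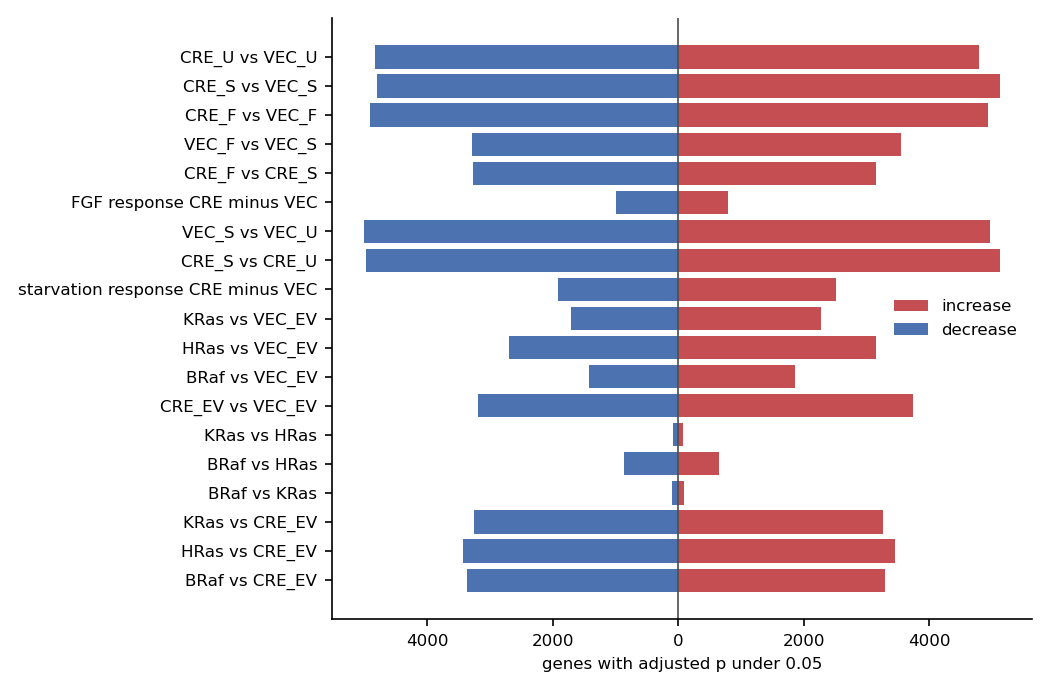
Genes past an adjusted p of 0.05 in each of the 19 comparisons, increases to the right and decreases to the left of 0. The counts run from 153 for KRas against HRas to 10103 for starvation in CRE cells.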

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

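All tests of explanations here, and counts over other splits, were chosen only after the results were seen. Results listed are differences in response between VEC and CRE cells, tested directly. Both tests use the starved libraries with opposite sign and are not independent. For FGF, 1791 genes differed. Genes with a lower response in CRE cells were Ccl2 (-2.35), Ccn2 (-1.32), Ier3 (-1.21), Dusp6 (-1.01), Hmga2 (-0.95) and Ccnd1 (-0.80), and Sox4 (1.32) and Trib3 (1.16) had a higher one. Median log2 differences of lists were -0.45 for chemokines and cytokines, -0.32 for Erk-induced output, -0.30 for E2F and DNA replication, -0.28 for cholesterol synthesis, 0.26 for Atf4 and amino-acid response genes and 0.12 for cartilage and bone markers. For starvation, 4432 genes differed, with Trib3 (-2.48), Mthfd2 (-1.50) and Atf5 (-1.31) lower and Egr3 (1.63), Dusp6 (1.12), Acat2 (1.11), Myc (0.99) and Lss (0.81) higher in CRE cells. The list medians were -0.74 for Atf4 and amino-acid response, 0.55 for cholesterol synthesis, 0.30 for immediate-early, 0.30 for E2F and DNA replication, 0.18 for Erk-induced output, 0.12 for Erk feedback genes, 0.12 for fibroblast and -0.0928 for neural crest and glial markers. With an estimated correlation, the immediate-early, E2F, Erk-induced output, fibroblast and neural crest lists lost their call, at adjusted p of 0.0977, 0.0977, 0.27, 0.149 and 0.0977.

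Regroupings of the libraries were counted for these 2 results. Of 100 splits, 11 gave as many genes as the real one for FGF, 1791, and the highest other gave 7431. For starvation it was also 11 of 100, with 4432 and 7006. In each case the 10 other splits kept the genotypes whole in one condition and exchanged most, not all, of the libraries in the other. They therefore largely counted the genotype difference itself. With each gene's genotype difference held, 1 of 100 regroupings, the real one, gave as many genes for both. The highest other gave 194 and 1213. No lower share was possible, so chance is not excluded.

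For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. Every other split also mixes both groups, so their real differences widen its spread and its count does not measure chance. The real split was 1 of the 10 with as many genes in each, and the highest other split gave 0 genes by edgeR except 2 for KRas against HRas, real 153, and 13 for BRaf against KRas, real 197. The other real counts are given in Results.

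Of the 3 patterns weighed, the first was that Spry2 kept more counts in CRE cells than Spry1 and Spry4. Undeleted cells among the CRE cells would leave equal shares of the 3 genes, and the highest share left of Spry1 or Spry4 in a library was 9.6% against a lowest Spry2 share of 18.7%, which argues against such cells as the whole cause. Reads from parts of Spry2 outside the deleted stretch cannot be told apart from intact transcript, at 18.7% or more, because the tables hold no positions.

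The response of the Atf4 list to starvation differed between VEC and CRE cells, adjusted p = 8.46e-05 with an estimated correlation. Its separate changes, up in VEC and down in CRE cells, lost their call that way, at 0.246 and 0.0789. Over 4 scalings, which shift medians by at most 0.0497 and so cannot test scaling, the median difference nearest to 0 was -0.734. It was -0.719 with 1 library left out, which argues against a single library. Other differences between these cells cannot be told apart from Spry loss, because each genotype has its own cells and 67.42% of tested genes differed when growing.

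The interferon-stimulated list rose with each oncogene against VEC_EV at the preset correlation, but with BRaf 22 of its 29 members did not pass. VEC_EV libraries, also transduced and selected, had list medians of -0.397 to 0.284 log2 CPM. CRE_EV libraries lay at 0.718 to 1.30, overlapping BRaf at 1.10 to 1.87. Joint variation of these genes between samples cannot be told apart from an oncogene effect. With an estimated correlation, their lowest adjusted p was 0.345, and no list passed with any oncogene (lowest 0.232). A possible response to transduced sequence that differs between vectors was not tested.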

How the results depend on the processing

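Library totals, the block with only the groups compared, and shared counts for FGF and starvation were chosen after the results were seen. Each of the 26 counts was recomputed with DESeq2 size factors, no filter on low counts, the DESeq2 test (not for lists), only the groups compared, replicate number as a block, counts thinned to the smallest library, library totals as the scaling, and the block with only the groups compared. Counts outside 1.5-fold of that reported follow, and the cause was not tested. With only the groups compared, KRas against VEC_EV gave 2533, KRas against HRas 36 and BRaf against KRas 0, with 872 at an unadjusted p under 0.05 in edgeR and 348 by the DESeq2 test over all groups. That test gave 449 for KRas against HRas. The block gave 5122 for BRaf against VEC_EV, 1097 for KRas against HRas, 3213 for BRaf against HRas, 666 for BRaf against KRas, 3796 for the genes shared by the 3 oncogenes and 2136 for those shared with Spry loss. The block with only the groups compared gave 5179, 1087, 4311 and 479 for the first 4 of these. Of 382 list tests, 176 passed, 54 with an estimated correlation and 291 by fry. For KRas against VEC_EV the block gave 5638 genes. Here replicate 2 fell below the pairing threshold, at 0.0921, although each library correlated best with that of its own number. Adjusted p was 0.0431, 0.0431 and 0.0794 for Erk-induced output, receptor tyrosine kinases and chemokines, against 0.0528, 0.0617 and 0.0465. Calls gained here had 0.579 with an estimated correlation, and elsewhere 0.342 to 0.622. Beyond these and those in the report, the block changed no list call in the second experiment. With 1 library left out, counts ran from 9149 to 9296, 9445 to 9614 and 9418 to 9583 for genotype in U, S and F, 6141 to 6447 and 5585 to 5873 for FGF in VEC and CRE cells, 9542 to 9653 and 9641 to 9757 for starvation, and 1481 to 1780 and 4000 to 4283 for the differences between these responses. They ran from 2777 to 4184, 4839 to 5327, 2142 to 3119 and 5917 to 6371 for KRas, HRas, BRaf and CRE_EV against VEC_EV, 17 to 846 for KRas against HRas, 794 to 1531 for BRaf against HRas and 54 to 320 for BRaf against KRas. Shared genes ran from 1591 to 2762 for the 3 oncogenes and 802 to 1536 with Spry loss, and lists past the threshold from 173 to 181. The low ends for BRaf against VEC_EV and for both shared counts left out VEC_EV replicate 3. Those for the oncogene pairs, and the high ends for pairs with KRas, are given in Results. The named genes were picked from a longer set with the stability of their calls in view, so their own stability says little. Of the 1694 pairs of gene and comparison that the naming rule gave and that passed, 130 lost their call under an alternative or without 1 library, 82 under an alternative and 121 without 1 library, and 0 changed sign. Of the 221 such pairs in the text, 2 lost it, Trpm5 and Lum in BRaf against KRas with only the groups compared, at log2 changes of 2.33 and -3.65. Part of the excess of shared genes over independent lists may come from the controls that the comparisons have in common. Such controls added a covariance of about 0.047 in simulated sets, against 0.332 to 0.903 measured, and their share of the count of genes was not tested. The majority of increases or decreases turned in an alternative fit for 15 of the 25 counts of genes and without 1 library for 7, in all for 17, of which 14 had 47 to 53% increases. Depth limits the low end, where 3 counts in a library came to 0.102 to 0.161 CPM.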
